A study of Mus musculus with 6 samples.

How the data were processed

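CTCF occupancy was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in G1E-ER4 cells, a mouse erythroblast line that lacks GATA1 and carries a GATA1 protein fused to the ligand-binding part of the estrogen receptor. Per the labels, the cells were treated with 100 nM estradiol for 24 hours, which switches the fusion protein on and starts erythroid differentiation. Of the 6 samples, 3 were CTCF ChIP libraries and 3 were input libraries. The ChIP libraries came from wild-type cells (1 library) and from 2 clonal sub-lines, D and C8, made with CRISPR/Cas9 so that BRD2 could not be detected (1 library each). BRD2 is a BET protein, a reader of acetylated histones. The input libraries were not used here.

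Per the submitters' processing notes, bcl2fastq 1.8.4 and Bowtie 1.0.0 were used and the genome build was mm9. The peak caller, its settings and the use of the inputs in peak calling are not given in the sources used here. The authors deposited 1 peak list per ChIP library, so peaks were called per library and not on pooled libraries. Each line of the deposited lists gives a position and 3 values in columns 7 to 9. Column 7 holds the authors' fold enrichment of the peak, a ratio whose denominator is not given in the sources used here. Column 8 holds the authors' −log10 p of the peak, whose lowest value is 5 in each list. Column 9, the q-value field of the deposited layout, holds a false discovery rate as a fraction. That rate falls as −log10 p rises, except that it rises again among the strongest peaks: 14 wild-type peaks, 34 peaks of clone D and 0 of clone C8 with a −log10 p of at least 100 have a rate above 0.05. These values belong to the authors' peak calling and were used here only to describe, rank or filter peaks within a list. The lists give no read totals, so the sequencing depth of each library is unknown here, and a peak missing from a list is a peak that was not called, not a site shown to be unbound.

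Lists were compared by overlap. Peaks of different lists were called shared when they overlapped by at least 1 bp, and regions are connected sets of overlapping peaks from the 3 lists. Peaks within a list did not overlap each other. The chance level was measured by moving every wild-type peak 50 kb downstream and counting overlaps again. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. With 1 wild-type library there is no test of wild type against BRD2-null cells, and no p-value is given: naming 1 of 3 libraries the wild type cannot give a share below 1 in 3. The difference between the 2 clones is the only measure of spread between libraries of the same genotype, and the clones may also differ by their clonal origin. Each list was divided by enrichment into 10 strength classes of equal size. For chromosomes and for windows of 2 Mb, the expected overlap was the overlap of autosomal peaks of equal strength, taken in 50 bins of the list by enrichment, and for chromosomes also in 50 bins by −log10 p. Positions are mm9, counted from 1.

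The regions named in the text were chosen by a rule fixed before the data were examined. It takes the 8 strongest wild-type-only peaks by enrichment, the 8 regions absent from wild type only with the best worse rank of the 2 clones, and the 5 strongest wild-type peaks found in all 3 lists. Other regions named were chosen after their values were seen. No mm9 genome or annotation was used here, so regions are given by position without gene names, and the planned gene lists and the planned search for the CTCF motif were not analysed here.

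The alternatives fixed before the data were examined were a reciprocal overlap of 50%, peaks extended by 500 bp, the upper 75% of each list, the upper 50% of the lists that hold a peak, lists cut to 29769 peaks by enrichment or by −log10 p, autosomes only, and each clone left out. A planned threshold on −log10 q was not run, because the deposited column holds the rate itself. Chosen after seeing the data were a false discovery rate of at most 0.05, a −log10 p of at least 10, and leaving out the start of chromosome 14.

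Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1. The overlap code was tested on simulated data: all 6150 simulated regions in 3 lists fell into the class they were made with. On the real lists, 12 of 12 overlap counts equalled those of bedtools 2.31.1. For the expected overlap by strength, a loss of 10 percentage points planted on chromosome X among the 40271 wild-type peaks was recovered as 11.1 points, and the largest difference on an autosome without a planted loss was 2.05 points.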

Results

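The CTCF ChIP-seq data compared differentiating wild-type G1E-ER4 erythroblasts with 2 independent clones of the line that express no detectable BRD2, and asked whether CTCF occupancy differs without BRD2. CTCF is a zinc finger protein that binds DNA at insulators and at the borders of chromatin domains. The wild-type list held 40271 peaks, clone D 29769 and clone C8 32308, a mean of 31039 ± 1795 (SD, n = 2) in the clones. The median peak width was 402 bp in wild type, 489 bp in clone D and 417 bp in clone C8, and the peaks covered 17.3, 14.9 and 13.9 Mb. The lists differed in how many weak peaks they held: 52.7% of wild-type peaks had a false discovery rate of at most 0.05 in the authors' column, against 94.8% in clone D and 85.4% in clone C8. By −log10 p the lists were closer: 44.2% of wild-type peaks, 26.2% of clone D peaks and 30.6% of clone C8 peaks had a value below 10. The depth of the libraries is unknown, and the wild type has 1 library.

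CTCF peak calls were largely shared between the lists at strong sites and less often shared at weak ones. Of the 40271 wild-type peaks, 59.8% were overlapped by a peak in both BRD2-null clones (95% interval 59.3 to 60.2). Clone D alone overlapped 63.1% (62.6 to 63.6) and clone C8 alone 65.3% (64.8 to 65.7), a mean of 64.2% ± 1.54 (SD, n = 2). After the wild-type peaks were moved by 50 kb, clone D overlapped 2.13% and clone C8 2.14%. With the clones as the reference, 80.6% of clone D peaks were found in both other lists (80.2 to 81.1) and 74.5% of clone C8 peaks (74.04 to 74.998). Wild type overlapped 85.1% of clone D peaks and 81.4% of clone C8 peaks. The clones overlapped each other at 87.9% of clone D peaks and 81.3% of clone C8 peaks. For clone C8, the share found in wild type and the share found in the other clone therefore differed by less than 1 percentage point. With all lists cut to their 29769 strongest peaks by enrichment, the share of wild-type peaks found in both clones was 75.8%. Clone D then overlapped 80.6% of wild-type peaks and clone C8 80.5%, against 85.1% of clone D peaks found in clone C8 and 85.4% of clone C8 peaks found in clone D.

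The share of wild-type peaks found in the clones rose with the strength of the peak. Each list was divided by enrichment into 10 strength classes of equal size, from 1 (weakest) to 10 (strongest). In class 1 of the wild-type list, 7.89% of peaks were overlapped in clone D (7.08 to 8.77) and 9.51% in clone C8 (8.62 to 10.5). In class 5 the shares were 63.4% and 68.5%, and in class 7 they were 95.03% and 96.85%. In class 10 they were 99.75% and 99.80%, and 0.174% of peaks were absent from both clones (0.0699 to 0.358). The clone lists followed the same course from a higher start: in class 1, 47.8% of clone D peaks and 38.8% of clone C8 peaks were overlapped in wild type, and in class 10 the shares were 100% and 99.97%. Weak calls also differed between the BRD2-null clones: in class 1, clone C8 overlapped 51.5% of clone D peaks and clone D overlapped 33.4% of clone C8 peaks.

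**Figure D1:**
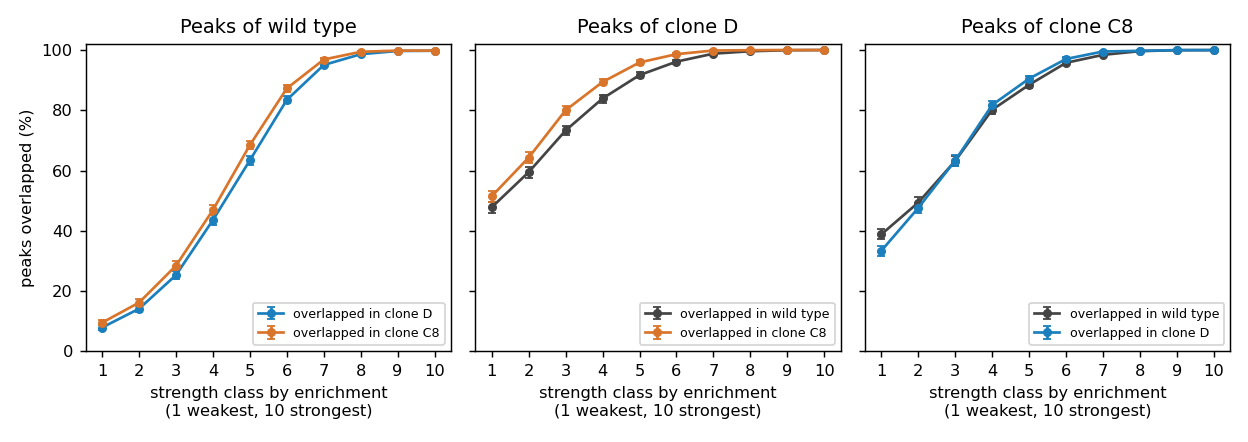
Share of the peaks of each list overlapped in each of the other lists (%), by strength class (10 classes of equal size by the authors' enrichment, 1 weakest); points are shares and bars are exact 95% binomial intervals, which cover counting error only. Wild-type peaks range from 7.89% overlapped in clone D in class 1 to 99.75% in class 10.

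The strongest wild-type sites were called in both clones. The 5 strongest wild-type peaks found in all 3 lists formed regions on chromosome 9 (121606448 to 121607302), chromosome 13 (111158565 to 111159408), chromosome 18 (75759302 to 75760070), chromosome 16 (11423250 to 11424355) and chromosome 3 (96091055 to 96091834). They were ranks 1 to 5 of the wild-type list, with enrichments of 295.39, 264.27, 251.77, 247.81 and 231.95. All 5 were also among the strongest peaks within each clone list, at ranks 1 to 99 of 29769 in clone D and 2 to 65 of 32308 in clone C8. In total, 23933 of 48367 regions (49.5%) were called in all 3 lists.

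Peaks called in wild type only were many and mostly weak. They numbered 12654, against 2274 regions called in clone D only and 3839 in clone C8 only. Of the wild-type-only peaks, 11748 had a −log10 p below 10 in the authors' column. Clone-only peaks were also mostly weak: 2094 of the 2274 in clone D and 3573 of the 3839 in clone C8 had such a value. Among the 13805 wild-type peaks with a −log10 p of at least 20, 32 were absent from both clones (0.232%, 0.159 to 0.327). By the same measure, 1 of 14989 clone D peaks (0.00667%, 0.000169 to 0.0372) and 7 of 14626 clone C8 peaks (0.0479%, 0.0192 to 0.0986) were absent from both other lists. With lists of equal length by enrichment, 4389 regions were called in wild type only, against 3010 in clone D only and 2973 in clone C8 only. At a −log10 p of at least 10, which left lists of similar length (22481 wild-type, 21977 clone D and 22436 clone C8 peaks), the counts were 2339, 1377 and 1519. The order turned at a false discovery rate of at most 0.05, which made wild type the shortest list and left 21210 wild-type, 28220 clone D and 27576 clone C8 peaks: 767 regions were then called in wild type only, 3467 in clone D only and 2738 in clone C8 only.

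The 8 strongest wild-type-only peaks had enrichments of 61.46 to 83.26 and ranked from 1116 to 4065 among the 40271 wild-type peaks. The strongest lay on chromosome 9 (19379799 to 19380040), with an enrichment of 83.26 and a −log10 p of 56.3. It was followed by a peak on chromosome 17 (56339231 to 56339595) with an enrichment of 71.28 and a −log10 p of 57.0. Next came peaks on chromosome 6 (132413660 to 132413894) and chromosome 1 (12634649 to 12635007), both with an enrichment of 69.39. The others lay on chromosome 2 (60240670 to 60240973), on chromosome 1 (45007980 to 45008209 and 174059276 to 174059668) and on chromosome 18 (6667481 to 6668168).

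Whether the same wild-type peaks were missed by both clones was compared with independent misses. Clone D missed 14866 wild-type peaks and clone C8 13990, and both missed 12654. Independent lists of these lengths would share 5164. Libraries that miss peaks independently at the rates seen within each of the 10 strength classes would share 10171. Both comparisons use the same wild-type list, which cannot be split, so part of the excess may come from that list. Peak strength also varies within a class. The comparison was not made with a clone list as the reference, so the excess cannot be read as particular to wild type.

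Regions called in both clones and not in wild type numbered 2167. The regions absent from clone D only numbered 2196 and those absent from clone C8 only 1304, so the count for wild type lay within the range of the clones in the lists as deposited. With lists of equal length by enrichment, 2803 regions were absent from wild type only, against 1375 absent from clone D only and 1404 absent from clone C8 only. Among regions with a −log10 p of at least 20 in the 2 lists that hold them, 20 of 12661 were absent from wild type (0.158%, 0.0965 to 0.244), 5 of 11811 from clone D (0.0423%, 0.0137 to 0.0988) and 4 of 11833 from clone C8 (0.0338%, 0.00921 to 0.0865). At a −log10 p of at least 10 the counts were 1757, 1261 and 992 for wild type, clone D and clone C8. Thresholds that left lists of unequal length gave other counts: in the upper 75% of each list, 890 regions were absent from wild type only, 2586 from clone D only and 1385 from clone C8 only, while at a false discovery rate of at most 0.05 the counts were 4905, 582 and 557. Without clone D, 6020 regions of clone C8 were absent from wild type, and without clone C8, 4448 regions of clone D.

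**Figure D2:**
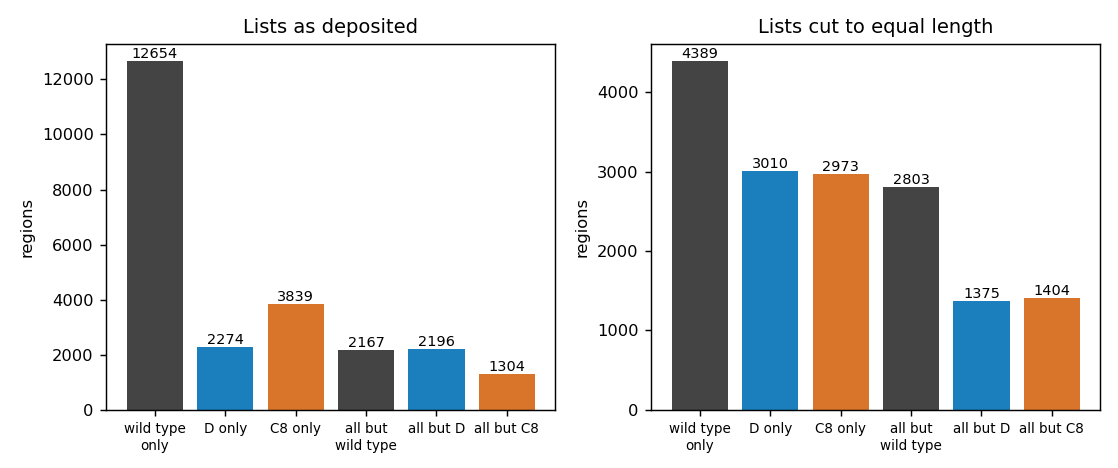
Number of regions called in a single list (3 bars on the left of each panel) and called in all lists but 1 (3 bars on the right), for the lists as deposited and for lists of 29769 peaks each. The wild-type-only class falls from 12654 to 4389 regions when the lists have equal length, and the scales of the panels differ.

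The 8 regions absent from wild type with the best ranks in both clones were of moderate strength. The first, on chromosome 19 (32586932 to 32587469), ranked 5441 of 29769 in clone D and 5841 of 32308 in clone C8, with enrichments of 31.28 and 40.05 within those lists. The others lay on chromosome 4 (39961576 to 39962111), chromosome 7 (30646600 to 30647132), chromosome 11 (68807904 to 68808425), chromosome 5 (4911775 to 4912320), chromosome X (137013609 to 137014080), chromosome 10 (127507398 to 127507935) and chromosome 9 (57068234 to 57068569). The lowest rank among the 8 was 11627 in clone D and 11473 in clone C8.

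Wild-type peaks on chromosome X were found in the clones less often than peaks elsewhere. Clone D overlapped 41.3% of the 1610 wild-type peaks on chromosome X and clone C8 43.5%. On the 19 autosomes the shares ran from 51.0% (chromosome 14) to 72.3% (chromosome 19) in clone D and from 54.1% (chromosome 14) to 74.4% (chromosome 11) in clone C8. Part of this followed from peak strength: wild-type peaks of equal enrichment on autosomes were overlapped at 46.4% in clone D and 48.6% in clone C8, which left differences of −5.07 and −5.09 percentage points for chromosome X. The autosomes ranged from −3.41 to 2.30 points in clone D and from −2.51 to 2.16 in clone C8, with chromosome 14 lowest in each. With equal −log10 p in place of enrichment, chromosome X differed by −4.64 points in clone D and −5.05 in clone C8, and chromosome 14 by −4.92 and −4.08, so in clone D chromosome 14 was then lower than chromosome X. Smaller deficits on chromosome X were also seen with the clones as the reference. At equal enrichment, clone C8 peaks on chromosome X differed by −3.06 points in their overlap with clone D, where the lowest autosome was at −2.35, and clone D peaks by −2.08 points in their overlap with clone C8, where the lowest autosome was at −3.46. Clone D and clone C8 peaks differed by −3.37 and −3.42 points in their overlap with wild type, where the lowest autosomes were at −2.73 (chromosome 18) and −5.73 (chromosome 8). At equal −log10 p, the differences between the clones were −1.27 (C8 in D) and −0.120 (D in C8), and those of clone peaks in wild type were −1.98 (D) and −2.53 (C8). On chromosome Y, wild type had 22 peaks, clone D 1 and clone C8 2. Both clone C8 peaks overlapped wild-type peaks and the clone D peak did not.

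**Figure D3:**
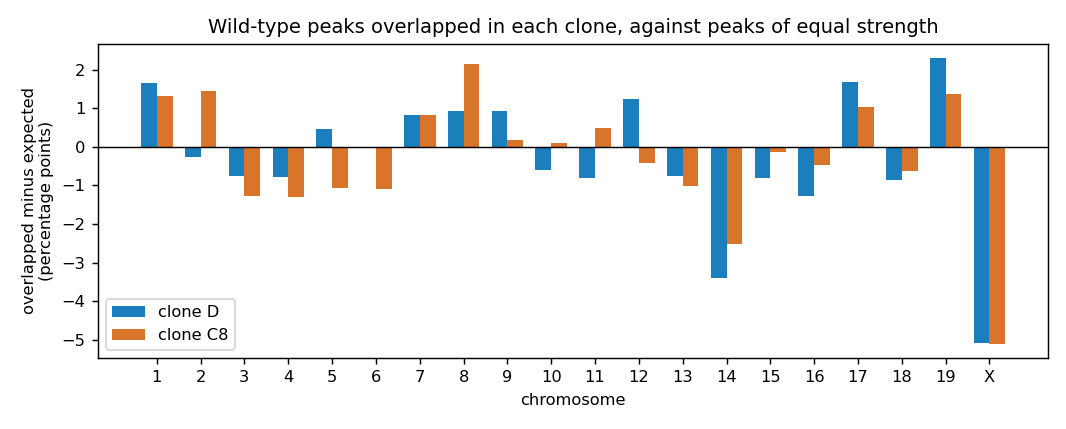
Share of wild-type peaks overlapped in each clone minus the share expected for autosomal peaks of equal enrichment (percentage points), by chromosome, with chromosome Y left out for its few peaks. Chromosome X lies at −5.07 in clone D and −5.09 in clone C8, and chromosome 14 is the lowest autosome in each.

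The deficit on chromosome 14 was concentrated near the start of the chromosome. Wild type had 280 peaks in the segment from 2000001 to 8000000, all between positions 3002420 and 7963841. Their median enrichment was 11.3, against 22.7 in the whole wild-type list. Clone C8 had 90 peaks in the same 6 Mb segment and clone D had 6. Clone C8 overlapped 18 of the 280 wild-type peaks and clone D 2.

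**Figure D4:**
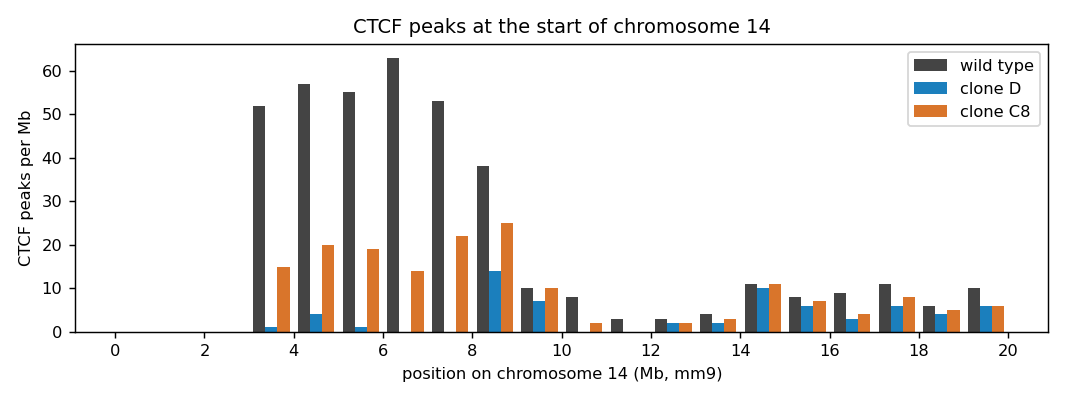
CTCF peaks per Mb along the first 20 Mb of chromosome 14 (mm9) in each list. Wild type has 52 to 63 peaks in each Mb from 3 to 8, clone C8 14 to 22 and clone D 0 to 4.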

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

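The thresholds on the false discovery rate and on −log10 p and the removal of the start of chromosome 14 were chosen after seeing the data; the other alternatives were planned. Each share was compared with the spread between the clones (1.54 percentage points) and each count with a factor of 1.5. Of 56 values under an alternative, 22 stayed within these limits and 34 moved. Autosomes only and the removal of the start of chromosome 14 moved none of the results. A reciprocal overlap of 50% gave shares of wild-type peaks of 57.6% in both clones and 61.4% in clone D, and extension by 500 bp gave 61.3% in both clones. In the upper 75% of each list the shares were 63.6% (both clones), 68.2% (D) and 72.2% (C8), with 6997 regions in wild type only and 890 in both clones and not in wild type. With the upper 50% in the lists that hold the peak, the shares were 94.0%, 95.3% and 96.6% and the counts 419 and 43. With lists of equal length the shares were 75.8%, 80.6% and 80.5% by enrichment and 76.1%, 80.1% and 80.6% by −log10 p, with 4389 and 4580 regions in wild type only. A false discovery rate of at most 0.05 gave 91.0%, 93.6% and 93.7%, with 767 regions in wild type only and 4905 in both clones and not in wild type. A −log10 p of at least 10 gave 79.5%, 84.0% and 85.1%, with 2339 regions in wild type only. By construction, these thresholds and the equal lengths remove weak peaks, and wild type held more of them. Leaving out each clone gave shares of 63.1 to 65.3% and 4448 to 6020 regions absent from wild type, since 1 list in place of 2 then had to hold the region.

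No paired analysis was possible because the labels give no replicate numbers and no result comes from a test. The planned threshold of a −log10 q of at least 5 was not run, because the column holds the rate itself. The gene lists with their alternatives and the CTCF motif were not run, because no mm9 genome or annotation was used here. Unknown depth limits every count: a weak site can be missing from a list because of fewer reads.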

Other observations

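The regions and windows in this part were chosen after the results were seen, and so were its tests, apart from that of a clone peak within 1 kb. The counts at equal list length were planned, but the bound they were held to was set after they were seen. Clone C8 had a peak on chromosome 15 (80857927 to 80858360) with an enrichment of 57.32 and a −log10 p of 91.0, rank 1588 of 32308, that overlapped no peak in wild type or clone D. Its next strongest private peak lay on chromosome 7 (126874768 to 126875148), with an enrichment of 32.38. The strongest private peaks of clone D lay close together on chromosome 5 (150086541 to 150087170 and 149690851 to 149691202), with enrichments of 27.1 and 20.58 and ranks of 7666 and 12126 of 29769. In the window of chromosome 5 from 150000001 to 152000000, clone C8 overlapped 31 of 50 clone D peaks, against 41.5 expected from strength.

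Several windows of 2 Mb stood apart from the rest. On chromosome X from 26000001 to 28000000, clone D overlapped 0 of 17 wild-type peaks (6.84 expected) and 0 of 11 clone C8 peaks (8.44 expected). From 26000001 to 32000000, wild type had 59 peaks, clone C8 33 and clone D 5, the first of clone D at 28003540. There 22.0% of wild-type peaks had a false discovery rate of at most 0.05, against 52.7% of the whole list. The share was 63.6% in clone C8, against 85.4%, while all 5 clone D peaks had such a rate. On chromosome 2 from 176000001 to 178000000, clone D overlapped 20 of 56 wild-type peaks (28.5 expected). On chromosome 9 from 88000001 to 90000000, clone D overlapped 16 of 42 wild-type peaks (24.1 expected) and 16 of 28 clone C8 peaks (22.0 expected). In the other direction, on chromosome 17 from 30000001 to 32000000, clone D overlapped 34 of 45 wild-type peaks (23.7 expected) and clone C8 overlapped 35 (24.9 expected). On chromosome 6 from 68000001 to 70000000, wild type overlapped 2 of 10 clone C8 peaks (8.00 expected). On chromosome 4 from 144000001 to 146000000, wild type overlapped 9 of 31 clone D peaks (18.8 expected) and clone C8 overlapped 10 (20.2 expected). On all of chromosome 8, wild type overlapped 76.6% of clone C8 peaks, a difference of −5.73 percentage points from the share expected from strength. Clone C8 peaks there were also low in clone D, at −2.35 the lowest autosome. In clone C8, clone D and wild-type peaks of chromosome 8 were the highest among autosomes (2.45 and 2.16). Clone D peaks there differed by −2.46 in wild type, and wild-type peaks by 0.922 in clone D. The 2 Mb windows above were picked from 976 to 1232 windows per comparison, so some would stand apart by chance.

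The first pattern weighed is the excess of wild-type peaks absent from both clones. Length of the list alone does not account for all of it. With equal lengths by enrichment, the wild-type-only count exceeded the larger clone-only count by 1379, while the clone-only counts were 3010 and 2973. Most of the excess was lost by the cut. The deposited lists gave 12654, 2274 and 3839 regions in wild type only, clone D only and clone C8 only. Weak calls near the caller's threshold stay open for most wild-type-only peaks: 11748 of the 12654 had a −log10 p below 10. The share absent from both other full lists was compared for peaks of like −log10 p. Clone peaks could be found in the wild-type list of 40271 peaks, wild-type peaks only in the clone lists of 29769 and 32308. That difference in length can by itself raise the wild-type share. From 10 to 15 it was 15.4% in wild type, 3.92% in clone D and 5.19% in clone C8. From 15 to 20 it was 2.18%, 0.709% and 0.623%. In both ranges wild type differed from the larger clone share by a larger factor than the clones from each other. These values cannot decide whether weak calls are the whole cause, with 1 wild-type library and lists of unequal length. At a −log10 p of at least 10 in every list, 2339 regions were wild-type-only, against 1377 and 1519 in the clones. Those lists had similar lengths. Like −log10 p was not like false discovery rate, though. A rate of at most 0.05 left 21210 wild-type, 28220 clone D and 27576 clone C8 peaks. There the order turned, with wild type the shortest list. At a −log10 p of at least 20 the shares were 0.232%, 0.00667% and 0.0479%. There the factor between the clones was larger, but it rests on 1 clone D peak and 7 clone C8 peaks. Loss of BRD2 stays open, because naming 1 of 3 libraries the wild type gives a share of at least 0.333. With equal lengths by enrichment, 2803 regions were absent from wild type only, against 1375 for clone D and 1404 for clone C8. At equal length, a list with more peaks of its own must miss more peaks that the others share. This count therefore largely follows from the wild-type-only excess and is not a separate sign that wild type differs.

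The second pattern is the crowd of wild-type peaks at the start of chromosome 14. A deletion of every copy of the segment in clone C8 is argued against by its 90 peaks there, if their reads come from the segment itself. A loss of some copies cannot be judged from a peak list. For clone D, with 6 peaks, a deletion cannot be told apart from a library with few calls there, since the list gives no read depth. Background calls in the segment, for example over repeated sequence, may account for the crowd: 8.93% of wild-type peaks there (25 of 280) had a false discovery rate of at most 0.05, against 52.7% of the whole list, and the share also fell in clone C8 (29 of 90, 32.2% against 85.4%) and clone D (2 of 6, 33.3% against 94.8%). Repeated sequence itself and loss of BRD2 were not tested for this segment.

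The third pattern is the set of 32 wild-type peaks with a −log10 p of at least 20 that neither clone list holds. A call of the same site a short distance away in a clone is argued against for most of them, as 9.38% (3 of 32) had a clone peak within 1 kb. Narrow pile-ups of reads stay open: the median width of the 32 was 431.5 bp. This lay between the median of 482 bp and the lower quartile of 396 bp of 640 common wild-type peaks of like −log10 p. By the positions given in the Results, most of the 8 strongest wild-type-only peaks were narrower than that lower quartile. The 32 peaks lay on 14 chromosomes, with at most 7 on 1 chromosome. For comparison, chromosome 2 held the largest share of the whole wild-type list, 7.89%. Loss of BRD2 also stays open for them, with 1 wild-type library and clones that may carry changes of their own.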
